A study of Caenorhabditis elegans with 2 samples.

How the data were processed

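Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the C. elegans transcription factor CEH-34 sits on DNA. Per the labels, the worms carried an integrated transgene that makes CEH-34 with a GFP tag at its C-terminus, chromatin was sheared by sonication, and the tagged protein was pulled down with an antibody against GFP. The chromatin came from whole late embryos collected 3.5 hours after synchronisation by bleaching. There were 2 biological replicates, prepared from separate biosamples, in 1 group, so no comparison between groups was made.

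The authors deposited peak lists, not reads. Per the file lists that accompany the peaks, each replicate has a list of candidate peaks and background, a further such list was called on both replicates' alignments together, and a thresholded list was derived from these by the irreproducible discovery rate (IDR), a measure of how repeatable the ranking of peaks is between replicates. Lists exist for the genome builds ce10 and ce11. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists hold a signal value for each peak, which is the peak caller's own height on a scale set per list, so signal was used only to rank and describe peaks within a list and to correlate the replicates over shared peaks, by ranks and by log2 values. The deposited lists also hold the −log10 of a q-value for each peak, which ran from 2.28 to 2.95 in the thresholded ce11 list and was not used in any test. All 2508 peaks of the thresholded ce11 list were the 2508 strongest peaks of the pooled candidate list. A control experiment is named in the labels and its data were not used here. Read depths were not analysed here, so the counting error behind a single signal value is unknown.

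Genes and sequences were taken from Ensembl release 115 and the RefSeq sequence of assembly WBcel235, which has the ce11 coordinates, and only the ce11 lists were joined to them. The ce10 lists served only for counts. A protein-coding gene was called bound when a thresholded summit lay within 1000 bp of an annotated 5′ end of any of its coding transcripts. Genes that share a divergent promoter were both counted. A summit was assigned to a promoter when it lay within 1000 bp upstream of a 5′ end, then to an exon, an intron or intergenic space, in that order of priority. Mitochondrial peaks were left out of all comparisons except those of the replicates.

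Peaks of 2 lists were called shared when their summits lay within 100 bp. Chance levels came from 100 seeded placements of peaks on their own chromosomes, or 10 where whole candidate lists were placed. Locations, chromosomes and structural RNA genes (tRNA, rRNA, snRNA and snoRNA genes within 200 bp of a summit) were compared between thresholded peaks and the other pooled candidates by two-sided Fisher's exact tests. The 20 gene lists were fixed before the data were examined, and each was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Where a list had no bound member, 0.5 was added to each cell for its odds ratio. Each list was also set against 10000 random lists matched on the number of distinct 5′ ends per gene. The symbol of 1 intestinal list member was not matched in the annotation, and histone symbols shared by several gene identifiers were counted once per identifier. The 7 fixed motifs and all 6-mers were searched on both strands within 50 bp of each summit and in a window of the same width centred 300 bp to the left. They were compared by two-sided exact McNemar tests, adjusted over motifs or over 6-mers, and the motifs were also counted in 100 shuffles of the central windows that keep dinucleotide counts. Candidate peaks within 20 kb of ceh-34 and unc-119 were ranked among 10000 random regions of the same length on the same chromosome. Intervals of shares are 95% Wilson intervals and cover counting error only. All these tests treat peaks or genes as units within lists made from 2 libraries, so they describe these lists and do not measure variation between animals.

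The genes named in the text were chosen by a rule fixed in advance. It takes genes within 1000 bp of the 20 strongest thresholded peaks that have a candidate summit within 100 bp in both replicates, up to 4 strongest bound members of each list, genes at the 10 strongest peaks with a sine oculis core within 50 bp, and always ceh-34, eya-1, unc-119, myo-2, rab-3 and eat-4. Other genes are marked as chosen later.

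Alternatives fixed in advance were windows of 500 and 2000 bp, the nearest or the most upstream 5′ end, a background of genes with a candidate peak, the 1245 strongest thresholded nuclear peaks, other definitions of shared peaks, the other flank, windows of 25 and 100 bp for motifs, regions of 10 and 40 kb around ceh-34, a distance of 500 bp to structural RNA genes, the ce10 lists, merged intervals, and the 2508 strongest candidates of each replicate alone. Leaving out peaks near structural RNA genes, stratifying genes by GC content, and using all candidates of each replicate around ceh-34 were added after the data were seen.

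Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with seed 1. The tests were checked on simulated data. Of 100 random lists of 30 genes drawn from 19973 genes with no effect, 7 passed an unadjusted p of 0.05, and of 100 lists planted at 4 times the odds, 81 did, with a median log2 odds ratio of 1.89. The motif test called 1 of 7 motifs between the left and right flanks, where no effect was planted, and called a sine oculis core planted in 10% of windows at 2490 peaks in 20 of 20 simulations. The core was planted in left flank windows, and smaller shares were not simulated, so the power for a smaller gain at summits is unknown. The stratified list test called 5 of 100 lists whose binding was set by the stratum alone, against 11 of 100 without strata.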

Results

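CEH-34 is a homeodomain transcription factor of the sine oculis homeobox family, known for its role in the nervous system of the C. elegans pharynx, the feeding organ. Its sites of occupancy were mapped by ChIP-seq in late embryos, 3.5 hours after synchronisation, from a strain that carries a GFP-tagged copy of ceh-34. The group held 2 biological replicates and no second condition. On the ce11 build, replicate 1 had 21725 candidate peaks, replicate 2 had 23509 and the pooled list had 29417. The thresholded list held 2508 peaks, of which 2490 were on nuclear chromosomes. Their median width was 450 bp, and their signal value, the authors' own height for a peak, ranged from 76.5 to 1522 with a median of 114.95. In 24 cases a second summit repeated an interval, and merging overlapping intervals left 2382 regions. The ce10 list held 2548 peaks.

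The first question was how far the replicates showed the same regions. The promoter regions of M01F1.9, K12H4.5 and the ribosomal protein gene rpl-3 held the 3 strongest nuclear peaks of the pooled list, and candidate peaks were present at all of them in each replicate. Of the 2508 strongest peaks of replicate 1, 1729 (68.9%, 95% interval 67.1 to 70.7) had a summit within 100 bp among the 2508 strongest of replicate 2. Random placement gave 0.679% on average and at most 1.24% in 100 placements. Across these 1729 shared peaks, log2 signal values correlated with Pearson's r of 0.826 and Spearman's rho of 0.738, a correlation over peaks, which are not independent replicates. Of the thresholded peaks, 2395 (95.5%, 94.6 to 96.2) had a candidate summit within 100 bp in both replicates. These peaks are the strongest of a list called on both replicates together, so this share describes the list and is no separate measure of the replicates' similarity. The median distance between the summits of the replicates at these peaks was 25 bp. The shared fraction moved with the definition, from 54.1% for summits within 50 bp to 74.7% for any overlap.

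**Figure D1:**
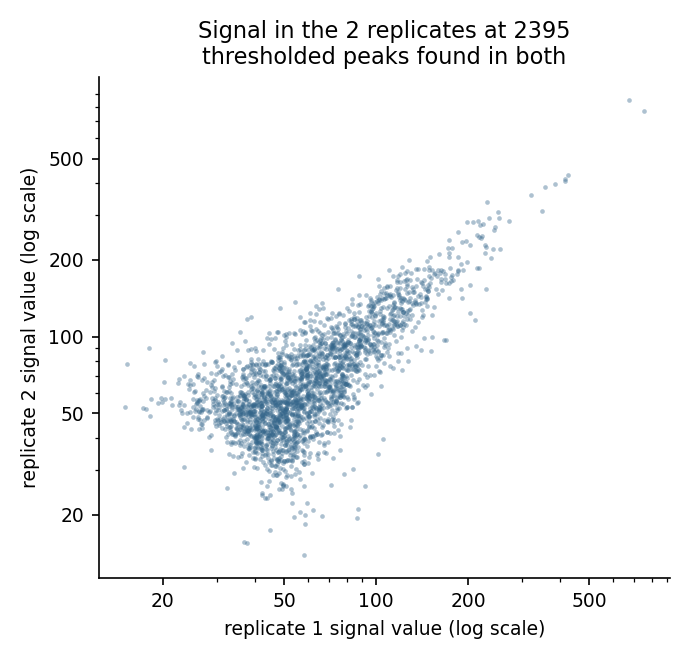
Signal value of replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), 1 point for each of the 2395 thresholded peaks with a candidate summit within 100 bp in both replicates. The scale of each axis is that of its own list; the strongest peaks, near M01F1.9 and K12H4.5, are at the upper right in both.

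The strongest peaks included those at the ribosomal protein genes rpl-3, rpl-15 and rpl-35. The peak of highest signal (1522) had its summit at chromosome III position 3500041, 984 bp from the 5′ end of M01F1.9 (WBGene00010815) and inside the neighbouring gene M01F1.8, which lies outside the naming rule and was named after its value was seen. The next (1515) was at III 8043962, 525 bp from the 5′ end of K12H4.5. The third (856) was at III 3867578, 276 bp upstream of rpl-3 (WBGene00004414), which encodes a large ribosomal subunit protein. A peak of signal 818 lay 58 bp from the 5′ end of tasp-1 and 727 bp from that of K01G5.10, and a peak of 658 lay between rpl-15 and K11H12.8. Further genes among the 20 strongest peaks found in both replicates were tos-1 (569), puf-9, a PUF family RNA-binding protein gene (557), eel-1, a HECT ubiquitin ligase gene (509), C04A11.5 (493), whose peak lay in a tRNA gene past the 3′ end of C04A11.5, the histone genes his-67 and his-68 with the Argonaute gene alg-5 (490), Y39E4B.6 (490) and rpl-35 (467). No protein-coding 5′ end lay within 1000 bp of 8 of these 20 peaks. The strongest of those 8, with a signal of 743, spanned V 12303450 to 12303872 in an intron of frm-7 that also holds the snoRNA gene C51F7.4; these host genes lie outside the naming rule and were named after their values were seen.

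Summits were concentrated in promoters and scarce in exons. Promoters held 1249 of the 2490 nuclear thresholded summits (50.2%, 48.2 to 52.1), against 27.3% of the 26906 other candidates and 21.96% at random placement (odds ratio 2.69, Fisher's exact test, adjusted p = 5.09e-117). Exons held 81 (3.25%, 2.63 to 4.03), against 22.5% of other candidates (odds ratio 0.116, Fisher's exact test, adjusted p = 1.58e-155). Introns held 19.8% against 27.5% (odds ratio 0.649, Fisher's exact test, adjusted p = 1.58e-17), and intergenic space held 26.8% against 22.7% (odds ratio 1.25, Fisher's exact test, adjusted p = 4.73e-06). A 5′ end of a coding gene lay within 1000 bp of 1414 summits (56.8%, 54.8 to 58.7), against 44.6% of other candidates (odds ratio 1.63, Fisher's exact test, p = 3.82e-31). Random placement gave 40.2% on average (37.8 to 42.9 over 100 placements). Many summits would thus lie in this window, which defines a bound gene, by position alone. Autosomal summits were more often in the central 50% of the chromosome, with 1204 of 1942 (62.0%) against 45.8% of other candidates (odds ratio 1.93, Fisher's exact test, p = 1.36e-42). Chromosome X held 548 thresholded summits, or 30.9 per Mb, close to chromosomes III (30.7) and I (29.7), and chromosome V held the fewest per Mb, 16.6. The X share was 22.01%, against 17.99% of other candidates (odds ratio 1.29, Fisher's exact test, p = 1.23e-06). The p-values for X and for chromosome centres are unadjusted over these 2 tests.

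**Figure D2:**
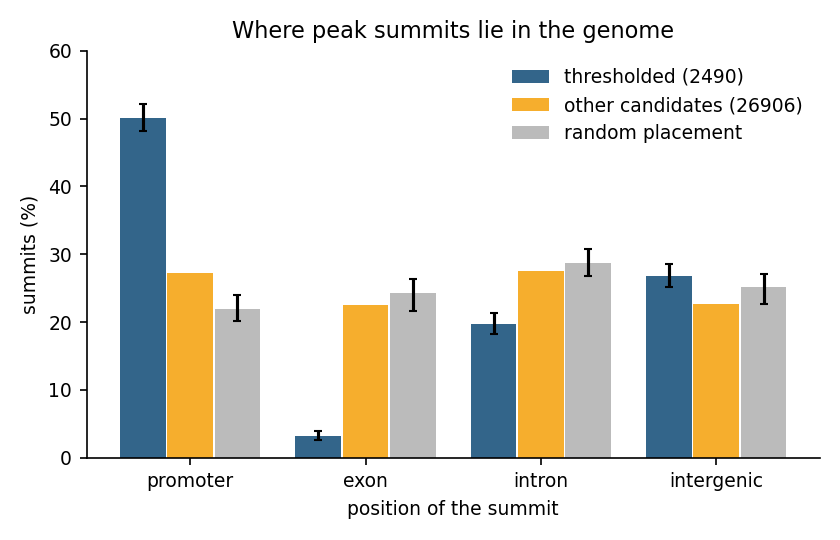
Percent of summits (y axis) in promoters, exons, introns and intergenic space (x axis) for 2490 thresholded peaks with 95% Wilson intervals, 26906 other candidates, and the mean of 100 random placements with their lowest and highest values. Thresholded summits reach 50.2% in promoters and 3.25% in exons.

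Of 19973 protein-coding genes, 1727 (8.65%, 8.26 to 9.04) were bound, and 9619 (48.2%) had any pooled candidate in the same window. Of the bound genes, 1296 were also bound when the 2508 strongest peaks of each replicate were used alone. With the 1245 strongest thresholded peaks, 922 genes were bound.

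Ribosomal protein genes stood out most, with 53 of 78 bound (67.9%, 56.96 to 77.3). Their strongest peaks were at rpl-3 (856), rpl-15 (658), rpl-35 (467) and rpl-20 (402). Body wall muscle genes followed, with 14 of 26 bound (53.8%, 35.5 to 71.2). They included unc-112 (signal 259), the kindlin gene of muscle attachments, the cofilin gene unc-60 (229), the troponin T gene mup-2 (157) and the actin gene act-4 (156). Members not bound included hlh-1, hnd-1, unc-120, deb-1 and pat-2. The bound member myo-3 had no candidate peak in replicate 1. These genes lie outside the naming rule and were named after their values were seen. The odds ratio was 23.1 for ribosomal protein genes (Fisher's exact test, adjusted p = 8.54e-37) and 12.4 for body wall muscle genes (Fisher's exact test, adjusted p = 2.95e-08), and both lay at percentile 100 of the matched random lists. Ribosomal protein genes had a mean GC content of 39.1% within 1000 bp of their 5′ ends, against 35.7% ± 3.37 (SD over 19973 genes) for all genes, and stratifying by GC decile, a step added after the data were seen, gave an odds ratio of 13.9 for them. Both lists passed under every alternative, with odds ratios down to 8.66 for ribosomal protein genes (nearest 5′ end only) and 6.23 for body wall muscle genes (1245 strongest peaks). Groups added after the planned lists were seen gave odds ratios up to 7.94, for small nuclear ribonucleoprotein genes. Heat shock protein genes gave 7.35 and aminoacyl-tRNA synthetase genes 1.09. All lay below the 12.4 of body wall muscle genes, but raised odds ratios were not particular to muscle genes.

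Genes used across the nervous system were bound more often than other genes, while pharyngeal neuron genes were not. Of 30 pan-neuronal genes, 10 were bound (33.3%, 19.2 to 51.2; odds ratio 5.31, Fisher's exact test, adjusted p = 0.00068). Against genes with a candidate peak the odds ratio was 3.28 (Fisher's exact test, adjusted p = 0.023), and with the 1245 strongest peaks it was 4.15 (Fisher's exact test, adjusted p = 0.0452). The 10 bound genes included the liprin gene syd-2 (259), unc-119 (211), the membrane fusion ATPase gene nsf-1 (205) and maco-1 (165). The gene rab-3 was not bound. Odds ratios of this size were not particular to neuronal genes. Groups added after the planned lists were seen gave 6.71 for translation factor genes and 4.71 for nuclear pore genes. Aminoacyl-tRNA synthetase genes gave 1.09. The peak at unc-119 lay in an intron, 106 bp from the 5′ end of an annotated transcript. The strain carries the unc-119(tm4063) allele and an integrated transgene, and an effect of these on the peak cannot be separated from binding. Of 30 pharyngeal neuron identity genes, only glr-8 was bound, with a signal of 96.6 (odds ratio 0.364, Fisher's exact test, adjusted p = 0.789), and eat-4, the vesicular glutamate transporter gene, was not. With the strongest peaks of replicate 1 alone glr-8 was not bound either, and the odds ratio, with 0.5 added to each cell, was 0.168. Of 19 transcription factor genes of pharyngeal neurons, only ceh-2 was bound (81.1), and its candidate peak was found in replicate 2 and not in replicate 1 (odds ratio 0.587, Fisher's exact test, adjusted p = 1). That odds ratio was 1.30 without replicate 1 and 0.263 without replicate 2. Without peaks near structural RNA genes ceh-2 was not bound, and the odds ratio, with 0.5 added to each cell, was 0.290. Intervals of the bound shares of both pharyngeal neuron lists were wide, 0.591% to 16.7% and 0.935% to 24.6%, and included the share of all genes.

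Of the 6 genes of the sine oculis family and its cofactors, eya-1 alone was bound. It encodes the Eyes absent protein, a known partner of sine oculis factors. Its summit at I 14231366 was 6 bp from the annotated 5′ end, with a signal of 79.7 that ranked 2342 among the 2490 nuclear peaks, and candidates were present in both replicates (odds ratio of the list 2.11, Fisher's exact test, adjusted p = 0.698). It was no longer bound when only the strongest peaks of replicate 2 or the 1245 strongest thresholded peaks were used. The list's odds ratio was then 0.849 and 1.59, values that come from adding 0.5 to each cell where no member is bound.

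Genes of pharyngeal muscle and organ identity had 5 of 19 members bound (26.3%, 11.8 to 48.8). These were the regulatory light chain genes mlc-2 (153) and mlc-1 (93.0), the organ identity factor pha-4 (139), the muscle homeobox gene ceh-22 (131) and the T-box gene tbx-2 (108), and the pharyngeal myosin gene myo-2 was not bound. The list members myo-1, myo-5, tnc-2, tnt-4 and tni-4 were not bound either. These genes and mlc-1 lie outside the naming rule and were named after their values were seen. The list did not pass the threshold (odds ratio 3.78, Fisher's exact test, adjusted p = 0.0571). It passed when only the nearest 5′ end counted (odds ratio 5.14, Fisher's exact test, adjusted p = 0.0252) and without replicate 1 (odds ratio 3.95, Fisher's exact test, adjusted p = 0.0487), but not without replicate 2 (odds ratio 3.67, Fisher's exact test, adjusted p = 0.0635). Against genes with a candidate peak it was further from the threshold (odds ratio 2.08, Fisher's exact test, adjusted p = 0.414), as it was with the 1245 strongest peaks (adjusted p = 0.182), a 2000 bp window (adjusted p = 0.169) and the most upstream 5′ end (adjusted p = 0.147), all in Fisher's exact tests.

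Serpentine chemoreceptor genes, which encode sensory receptors, were bound far less often than other genes. Only 9 of 1237 were bound (0.728%, 0.383 to 1.38; odds ratio 0.0726, Fisher's exact test, adjusted p = 1.95e-36), the strongest being sre-23 (456) and sre-1 (268). Only 227 of the 1237 had any candidate peak, and against genes with a candidate the odds ratio was 0.184 (Fisher's exact test, adjusted p = 2.08e-09). Peptide genes of the FMRFamide-like, neuropeptide-like and insulin-like families had 4 of 140 bound, namely nlp-4 (278), flp-23 (138), ins-39 (132) and nlp-68 (101.04), an odds ratio of 0.309 (Fisher's exact test, adjusted p = 0.0324). The nlp-4 summit lay past the 3′ end of that gene. Without peaks near structural RNA genes, 2 of the 140 stayed bound (odds ratio 0.163, Fisher's exact test, adjusted p = 0.00571). The call of peptide genes was lost in 4 of the alternatives, with adjusted p from 0.0748 to 0.633 in Fisher's exact tests. Histone genes had 14 of 72 bound (19.4%, 11.95 to 30.03; odds ratio 2.56, Fisher's exact test, adjusted p = 0.0183), led by his-67 and his-68 (490) and his-61 and his-62 (273). The members of each of these pairs share a divergent promoter and were called by the same summit. The test and the interval count such a peak more than once, so the genes are not independent units. Histone genes also exist in near-identical copies, so which copies carry the signal is uncertain. The histone call was lost when genes were stratified by GC decile (odds ratio 1.20, adjusted p = 0.84) or when only the nearest 5′ end counted (odds ratio 1.80, Fisher's exact test, adjusted p = 0.407).

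The remaining lists did not pass the threshold. No member was bound among 24 intestinal, 25 epidermal and 6 Hox genes. The odds ratio of epidermal genes, 0.207 with 0.5 added to each cell, was 0.427 without replicate 2 (Fisher's exact test, adjusted p = 0.925). Germline genes had 2 of 29 bound (cgh-1, spo-11), cilium genes 2 of 33 (daf-19, dyf-3), and genes of touch receptor, GABA and dopamine neurons 2 of 16 (ast-1, snf-11). The list of pharyngeal gland, arcade and cuticle genes had 1 of 20, the junction gene ajm-1 (154). Homeobox genes named ceh had 6 of 63 bound, including ceh-39 (128), ceh-38 (125) and ceh-20 (101.36), the last with a candidate in replicate 1 and not in replicate 2. Nuclear hormone receptor genes had 16 of 269, led by nhr-48 (335) and nhr-59 (210). Collagen genes had 10 of 156, led by col-85 (252) and col-72 (177), with an odds ratio of 0.722 (Fisher's exact test, adjusted p = 0.698) that fell to 0.436 among genes with a candidate peak (Fisher's exact test, adjusted p = 0.0267) and was 1.34 without replicate 2 (Fisher's exact test, adjusted p = 0.484).

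**Figure D3:**
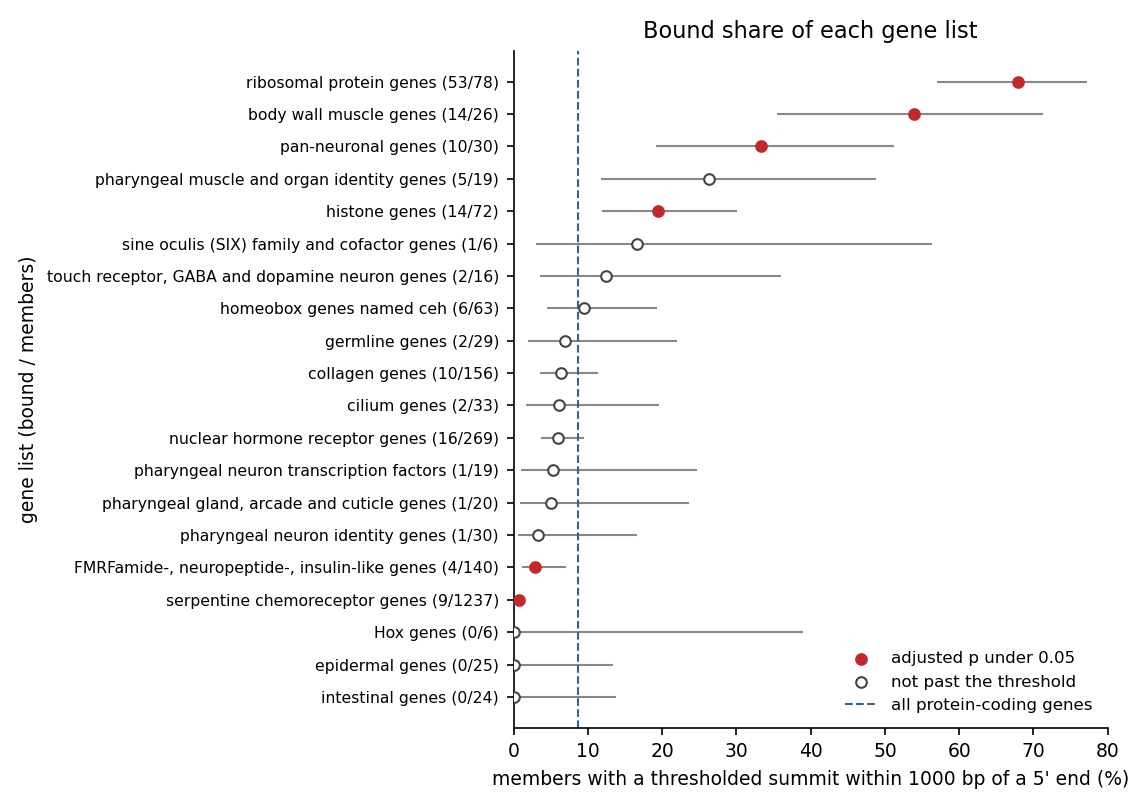
Percent of the members of each of the 20 gene lists that were bound (x axis), with 95% Wilson intervals and the number bound out of all members beside each name. Filled points passed an adjusted p of 0.05, and the dashed line marks the 8.65% of all protein-coding genes; ribosomal protein genes reach 67.9% and body wall muscle genes 53.8%.

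A further question was whether DNA sequences known for sine oculis proteins occur at the summits. The sine oculis core TGATAC was found within 50 bp of 80 summits (3.21%, 2.59 to 3.98) and in the left flank of 81 (3.25%), a difference that did not pass (exact McNemar test, adjusted p = 1). Shuffled central windows gave 2.61% on average, with a range of 1.89% to 3.49%. The left flanks had a mean GC content of 36.2%, against 48.9% in the central windows, so the flank comparison does not hold base composition equal. Against other candidates within GC deciles, in a test chosen later, the odds ratio of the core was 1.55 (1.21 to 1.97). The MEF3-type site TCAGGTT was found at 1.53% of summits and 1.08% of flanks (exact McNemar test, adjusted p = 0.233). The strongest peaks with that core near the summit were those at rpl-35 (467), between lin-54 and rpl-12 (343), at vig-1 (260), at F28F9.2 (248) and between rps-12 and ska-3 (226), and 5 of the 10 strongest had no coding 5′ end within 1000 bp.

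Of the 7 motifs, the GA repeat GAGAGA had the largest ratio of summits to flanks, at 716 summits (28.8%, 27.01 to 30.6) against 205 flanks (8.23%; exact McNemar test, adjusted p = 5.74e-78), and shuffled windows gave 13.4%. The E-box CAGCTG was at 3.94% of summits and 1.45% of flanks (exact McNemar test, adjusted p = 6.67e-08). GATA sites (WGATAA) were less frequent at summits, 4.74% against 14.9% (exact McNemar test, adjusted p = 3.01e-33), as was the homeodomain site TAATTA, 1.25% against 5.86% (exact McNemar test, adjusted p = 3.66e-19). The ratio for TAATTA, 0.215, was 0.109 with windows of 25 bp and 0.344 with 100 bp. It was 0.251 without replicate 1 and 0.325 without replicate 2. Shuffled windows gave 8.05% for GATA sites (6.83 to 9.44) and 1.498% for TAATTA (0.803 to 1.97), so for TAATTA the summits lay within the range of their base composition. The forkhead site of PHA-4 (TRTTKRY) was at 24.8% of summits and 26.8% of flanks (exact McNemar test, adjusted p = 0.16), and passed as less frequent at summits against the right flank (exact McNemar test, adjusted p = 0.000731) and without replicate 1 (exact McNemar test, adjusted p = 0.0072). Shuffled windows gave 15.98% for it (13.6 to 17.6), below the share at summits. Among all 6-mers, 766 were more frequent at summits and 519 less frequent. Of the 766, 738 had at least 3 G or C bases, against 49 of the 519. After GAGAGA and AGAGAG the enriched 6-mers with the smallest p were CGTCTC (18.3% against 4.06%) and AGAGAC (18.7% against 4.90%), and among depleted 6-mers it was AAAAAT (15.6% against 45.6%). The mean GC content was 48.9% in the central windows and 36.2% in the left flanks.

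**Figure D4:**
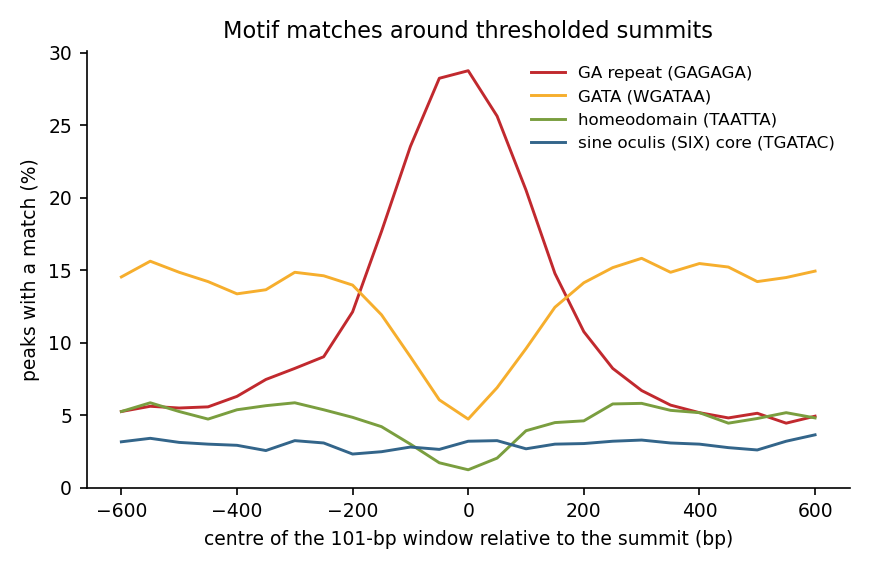
Percent of the 2490 thresholded nuclear peaks (y axis) with a match to each of 4 motifs within 50 bp of a position, by the distance of that position from the summit in bp (x axis). GA repeats reach 28.8% at the summit, GATA and homeodomain sites dip to 4.74% and 1.25%, and the sine oculis core stays near 3%.

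Genes of structural RNAs were frequent neighbours of the peaks. Such a gene lay within 200 bp of 259 of 2490 summits (10.4%), against 1.59% of other candidates (odds ratio 7.20, Fisher's exact test, p = 8.72e-103). Of these, tRNA genes accounted for 174 (odds ratio 7.55, Fisher's exact test, p = 1.32e-72), snoRNA genes for 68 (odds ratio 6.27, Fisher's exact test, p = 3.27e-26) and snRNA genes for 17 (odds ratio 4.29, Fisher's exact test, p = 6.35e-06).

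The ceh-34 gene itself had no thresholded summit within 1000 bp of a 5′ end and so was not called bound. It lies at V 5315496 to 5319577, and the surrounding region with 20 kb on each side held 3 pooled candidates and no thresholded peak, at percentile 16.9 of random regions on V, which held 9.81 on average. With the strongest peaks of replicates 2 and 1 alone the percentile was 28.1 and 28.95, and with 10 and 40 kb on each side 7.12 and 26.5. With all candidates of replicates 1 and 2 it was 6.24 and 32.1. The regions behind 28.1, 28.95 and 7.12 held 0 candidates, so these values are floors. Of the random regions, 56.2%, 57.9% and 14.2% held 0 as well. The strain also carries a tagged copy of ceh-34 in an integrated transgene. Its effect on peaks here cannot be separated, so absence of binding is not shown. No pooled candidate summit lay between V 5300539 and V 5400833, a gap of 100.3 kb; 6 of the 4680 gaps on the chromosome were at least as long, and the longest was 239 kb. The corresponding region around unc-119 held 21 candidates, at percentile 78.5, and the other settings put it between 41.1 and 63.7.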

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

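The thresholded list holds 18 peaks on the mitochondrial genome, which no comparison of genes, motifs or locations used. They were singled out because a signal appears in data outside the main measurement and their number exceeds the 3 that a count of 0 allows. That limit only flags results and is no test of binding. Read depths and control data were not used, so the values below do not show binding there. Their signal ranged from 90.6 to 826 with a median of 267, against a median of 114 for nuclear thresholded peaks, and they covered 38.0% of the 13794 bp of that genome. The candidate lists held 20 mitochondrial peaks in replicate 1 and 18 in replicate 2.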

How the results depend on the processing

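In all, 295 alternatives were run over 39 results. Of these, 246 kept the direction and the side of the threshold, or stayed within the limit set for a count or share. In 25 the odds ratio or ratio crossed 1, and in 0 of these did either value pass the threshold. Those that stratify by GC or leave out peaks near structural RNA genes, and those with all candidates of each replicate around ceh-34, were chosen after seeing the data. The shared fraction of the replicates was 54.1% for summits within 50 bp, 57.1% with doubled list lengths, 73.2% with halved ones and 74.7% for any overlap. The 1245 strongest peaks gave 922 bound genes. Peptide genes were no longer called with the most upstream 5′ end (odds ratio 0.339), the nearest 5′ end (0.420), the 1245 strongest peaks (0.451) or a 2000 bp window (0.485). Histone genes were no longer called with the nearest 5′ end (1.80) or stratified by GC (1.20). Collagen genes became called against genes with a candidate peak (0.436) and stratified by GC (0.362). Pharyngeal muscle and organ genes became called with the nearest 5′ end (5.14) and without peaks near structural RNA genes (4.06), and leaving out replicates gave 3.67 to 3.95, called only without replicate 1. The PHA-4 site became called as less frequent against the right flank (ratio 0.850), and leaving out replicates gave 0.875 to 0.952, called only without replicate 1. Odds ratios of lists not called with the planned settings crossed 1 when replicates were left out in turn: collagen 0.836 to 1.34, cilium 0.320 to 1.10, germline 0.394 to 1.18, pharyngeal neuron transcription factors 0.263 to 1.30, gland, arcade and cuticle 0.540 to 1.23, ceh homeobox 0.884 to 1.16, sine oculis family 0.849 to 2.05, and touch receptor, GABA and dopamine 0.684 to 0.736 (from 1.51). The touch receptor list also crossed with the 1245 strongest peaks (0.625) and a 500 bp window (0.976), and the gland list with the 1245 strongest (1.09). The ceh list crossed against genes with a candidate peak (0.806), with windows of 2000 bp (0.745) and 500 bp (0.731), and without peaks near structural RNA genes (0.977). Hox genes, with none bound in any of these, crossed with the nearest 5′ end (1.10), the 1245 strongest peaks (1.59) and a 500 bp window (1.13). The sine oculis core crossed from 0.988 with windows of 100 bp (1.09) and 25 bp (1.16), the 1245 strongest peaks (1.20) and without peaks near structural RNA genes (1.08), and leaving out replicates gave 1.01 to 1.19. The percentile of ceh-34 was 7.12 with 10 kb on each side and 26.5 with 40 kb. It was 6.24 and 32.1 with all candidates of replicates 1 and 2, and 28.1 to 28.95 with replicates left out in turn. Regions with 0 candidates gave 7.12, 28.1 and 28.95, which are floors. Among called lists, the odds ratio of ribosomal protein genes fell to 8.66 with the nearest 5′ end, 11.3 against genes with a candidate peak, 12.6 with the 1245 strongest peaks and 15.4 to 16.8 with replicates left out. That of body wall muscle genes fell to 6.23 with the 1245 strongest, 8.05 against genes with a candidate peak and 10.3 to 11.1 with replicates left out. The cause of these changes was not tested. The 3 lists with no bound member have no stratified odds ratio. No paired analysis was possible because there is 1 group. The depth of the libraries was not analysed here.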

Other observations

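Further gene groups were defined by symbol after the planned lists were seen, and these tests were all chosen only then. Translation factor genes had 12 of 31 members bound (odds ratio 6.71, Fisher's exact test, adjusted p = 4.74e-05 over the 19 added groups), with eif-3.B, eif-3.E and the elongation factor gene eef-1A.2 among the strongest. Heat shock protein genes had 9 of 22 bound, including hsp-1, hsp-60 and hsp-90 (odds ratio 7.35, Fisher's exact test, adjusted p = 0.000294). Proteasome genes had 10 of 33 bound, led by rpn-3 and rpn-7 (odds ratio 4.61, Fisher's exact test, adjusted p = 0.00125), and nuclear pore genes 8 of 26, led by npp-6 and npp-8 (odds ratio 4.71, Fisher's exact test, adjusted p = 0.00368). Vacuolar ATPase genes and Rab GTPase genes each had 6 of 20 bound (odds ratio 4.54, Fisher's exact test, adjusted p = 0.0132). Actin and tubulin (odds ratio 4.41), small nuclear ribonucleoprotein (7.94), ubiquitin-conjugating enzyme (3.31) and cytochrome P450 genes (0.144) also passed. Aminoacyl-tRNA synthetase genes had 3 of 32 bound (odds ratio 1.09, Fisher's exact test, adjusted p = 0.895). Other groups that did not pass were bHLH (0.919), T-box (0.587), innexin (1.11), twk potassium channel (0.773) and PUF genes (1.17). Acetylcholine receptor-like genes, with 0 of 21 bound, did not pass either. Large families with few bound members were C-type lectin genes, 2 of 240 (odds ratio 0.0877, Fisher's exact test, adjusted p = 3.37e-06), and F-box A genes, 3 of 170 (odds ratio 0.188, Fisher's exact test, adjusted p = 0.00125).

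The 6-mers ACGCAG, GACGCA and, on the other strand, CGTCTC overlap in a longer word. GAGACGCAGA was found within 50 bp of 152 summits (6.10%), in 10 left flanks (0.402%) and at 1.18% of other candidates (exact McNemar test, unadjusted p = 9.45e-34, chosen as the leading word of its length). On chromosome X it was at 3.28% of summits and on autosomes at 6.90%.

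All tests of explanations that follow were chosen only after the results they concern were seen, and that on tRNA-near peaks with a unique sequence also after the other tests. For the binding of ribosomal protein and body wall muscle genes, the tables argue against GC content near 5′ ends as the whole cause. Within GC deciles the odds ratio was 13.9 (8.54 to 22.7) for ribosomal protein genes and 9.36 (4.12 to 21.3) for body wall muscle genes. Leaving out peaks near structural RNA genes gave 23.4 (14.6 to 37.6) for ribosomal protein genes, and 0 of their 53 bound genes (0%, at most 6.76%) had a central sequence mostly found elsewhere, which argues against reads shared between near-identical copies. A signal that strongly transcribed genes give for any tagged protein may still be present and stays open, since control data were not used here. No biological explanation was tested, because the design has 1 group.

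The sine oculis core was no more frequent at summits than in flanks, and the base composition of the GC-rich summits could hide a difference. Compared with other candidates within GC deciles, thresholded summits had the sine oculis core more often, with an odds ratio of 1.55 (1.21 to 1.97), which includes the bound of 1.5 set before the test was run and so leaves this open. Dilution by peaks at GA repeats, structural RNA genes and ribosomal protein genes also stays open. Without them, 1503 peaks had a ratio of summit-only to flank-only matches of 1.04 (0.699 to 1.54; exact McNemar test, p = 0.923). No biological explanation was tested.

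For the peaks near tRNA genes, GC content of the summits is argued against, with an odds ratio of 6.46 (5.21 to 8.01) within GC deciles. Reads shared between near-identical copies may contribute at 58 of the 174 peaks (33.3%, 26.8 to 40.6), whose central sequence is mostly found elsewhere in the genome, and there it cannot be told apart from binding. Among peaks with a mostly unique central sequence, 116 lay near a tRNA gene and the odds ratio was 6.14 (4.88 to 7.73). The excess near tRNA genes therefore did not rest only on the 58 peaks. Only the central sequence was checked for copies, and the tRNA gene may lie partly or wholly outside it. This split thus cannot decide whether shared reads contribute at the 116 peaks, and that stays open. No biological explanation was tested.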
